A study of Mus musculus with 59 samples.

How the data were processed

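Livers of wild-type (wt) mice and of mice with an E2f3a knock-out (3aKO), an E2F1 knock-in (1KI) or an E2F3b knock-in (3bKI), all on a mixed background, were taken at 4 weeks of age. Per the labels, Trizol was used to extract RNA, 5 µg of total RNA was labelled as biotin cRNA, and each sample was hybridized to a mouse expression array of 45101 probe sets. The locus of the knock-ins, the pairing of arrays across genotypes and the dates of hybridization are not given in the sources used here.

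The deposited values are log2 expression values, normalized across arrays by the authors with a method not given in the sources used here. The log base was taken from the values themselves, which run from 2.13 to 15.06 with 2 decimals. The 59 columns hold 37 arrays in 2 normalizations. The first holds 12 wt, 10 3aKO and 10 1KI arrays, and the second holds the same 22 wt and 3aKO arrays, normalized anew, with 5 3bKI arrays. Values of the shared arrays differed little between them, with a lowest correlation per array of 0.999 and a largest difference of 0.89 for a probe set. Array medians lay between 5.91 and 6.00 in the first and between 5.83 and 5.96 in the second. 1KI was compared with wt and 3aKO within the first normalization, 3bKI with wt and 3aKO within the second, and 3aKO with wt in the first. 1KI and 3bKI were not compared with each other, since no normalization holds both.

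Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, and 64 were controls. By Entrez ID 34741 of those with 1 symbol matched the RefSeq annotation of GRCm38.p6, which was used for gene names and neighbours alone, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests. Each of 18193 genes was represented by its probe set with the highest mean over all arrays of a normalization, which was a choice among several for 9010 genes. No filter on low signal was applied in the comparisons reported first.

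Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend) over all arrays of a normalization, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. Errors of log2 changes are the moderated standard errors of limma. Gene lists, 33 in number with 659 members of which 597 were tested, were compared with all other genes by the camera test of limma with a preset correlation of 0.01, adjusted over 165 tests (33 lists in 5 comparisons), and again with the correlation estimated from the data. Genes were named by a fixed rule. E2f1, E2f2, E2f3, Ccne1, Cdc6, Mcm6, Cdkn1a and Afp were always named. Of the called genes above the median signal, the 10 highest and 10 lowest log2 changes were named. Members of the sex chromosome gene list were left out, but other genes of these chromosomes were not. Of each passing list up to 4 members with the smallest p were named. Other list members were named after their values were seen. The lists, the rule, the comparisons and the thresholds were chosen before the data were examined.

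The knockout score took the 100 genes with the strongest difference between odd-numbered 3aKO and wt arrays and placed each other array on a scale from even-numbered wt (0) to even-numbered 3aKO (1). Scores and control measures were compared by 2-sided permutation tests, exact where the number of regroupings allowed it, with Benjamini-Hochberg adjustment over 30 tests for the control measures. Overlaps of called genes between comparisons that share wt arrays were set beside 50 simulations in which the genotypes did not differ. Genes near E2f3 were counted by a 2-sided Fisher's exact test.

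Control signals were computed per array. They were the mean of 18 hybridization control and of 24 poly-A control probe sets, the 3' minus 5' difference averaged over Gapdh and Actb as a measure of RNA integrity, and Xist and Y-linked genes. An array was placed at the higher hybridization control level when it reached the lowest knock-in array of its normalization.

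Each model was tested on simulated data with the spread of these arrays, in 20 simulations with 200 changed genes among 18193. Of changes of 0.5 on the log2 scale, 93.2% were recovered in 3aKO against wt, 92.9% in 1KI against wt, 92.2% in 1KI against 3aKO, 87.9% in 3bKI against wt and 84.8% in 3bKI against 3aKO, and of changes of 1 at least 97.6% in each. False calls made up between 4.36% and 5.29% of the calls. A list shifted by 0.3 passed in 20 of 20 simulations of each comparison. The simulated genes varied independently of each other, without hybridization control levels or sex, so these rates need not hold for the real arrays.

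The comparisons were repeated with 1 choice changed at a time. The changes were a fit on the compared groups alone, eBayes with a trend, genes above the median signal, all probe sets, the mean of the probe sets of a gene, no _x_at probe sets, a further quantile normalization, equal array medians, array weights, a sex index or RNA integrity as a covariate, replicate numbers as a block, the other normalization and each array left out. After the control signals had been seen, the hybridization control level as a block, alone and with a sex index, its levels alone and an average of similar wt arrays were added. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the plots.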

Results

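Liver RNA of 1-month-old mice was compared between wild type (wt, 12 arrays), E2f3a knock-out (3aKO, 10 arrays), E2F1 knock-in (1KI, 10 arrays) and E2F3b knock-in (3bKI, 5 arrays), to ask how each altered E2F allele changes gene expression in the young liver. Of 18193 genes tested with limma, 32 passed an adjusted p of 0.05 in 3aKO against wt, 5026 in 1KI against wt and 5318 in 3bKI against wt. The median size of the called changes was 0.36, 0.26 and 0.34 on the log2 scale. The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

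The 4 genotypes differed in control signals that were measured beside the liver genes. Spiked-in hybridization controls had a mean log2 signal of 10.4 ± 0.50 (SD, n = 12) in wt, 10.2 ± 0.12 (n = 10) in 3aKO and 11.3 ± 0.24 (n = 10) in 1KI, and of 11.6 ± 0.29 (n = 5) in 3bKI. Wt replicates 1 and 2 had the level of the knock-in arrays and the other 10 wt arrays that of 3aKO. Poly-A controls, added before labelling, stood at 13.8 ± 0.04 in 3bKI and at 9.04 ± 0.39 in the wt arrays normalized with them. They were also higher in 1KI than in 3aKO, by 0.614 (n = 10 and 10, permutation test, adjusted p = 0.0025). The difference between 3' and 5' probe sets of Gapdh and Actb, a measure of RNA integrity, was 0.314 ± 0.038 in 3bKI and 0.559 ± 0.050 in wt (permutation test, adjusted p = 9.7e-04). In the other normalization it was higher in 3aKO than in wt by 0.067 (n = 10 and 12, permutation test, adjusted p = 0.030). With it as a covariate all 32 calls in 3aKO were kept. The slope of that fit rests largely on 1KI replicate 6 (1.75), so the kept calls do not decide whether RNA integrity plays a part. Xist and Y-linked genes split the arrays into 5 and 7 in wt, 5 and 5 in 3aKO, 5 and 5 in 1KI, and 2 and 3 in 3bKI. Wt replicates 1 and 2 both had Y-linked signal. Fits with the hybridization control level as a block therefore compare knock-in arrays of both kinds with 2 wt arrays of 1 kind, and a further fit took a sex index beside the block.

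**Figure D1:**
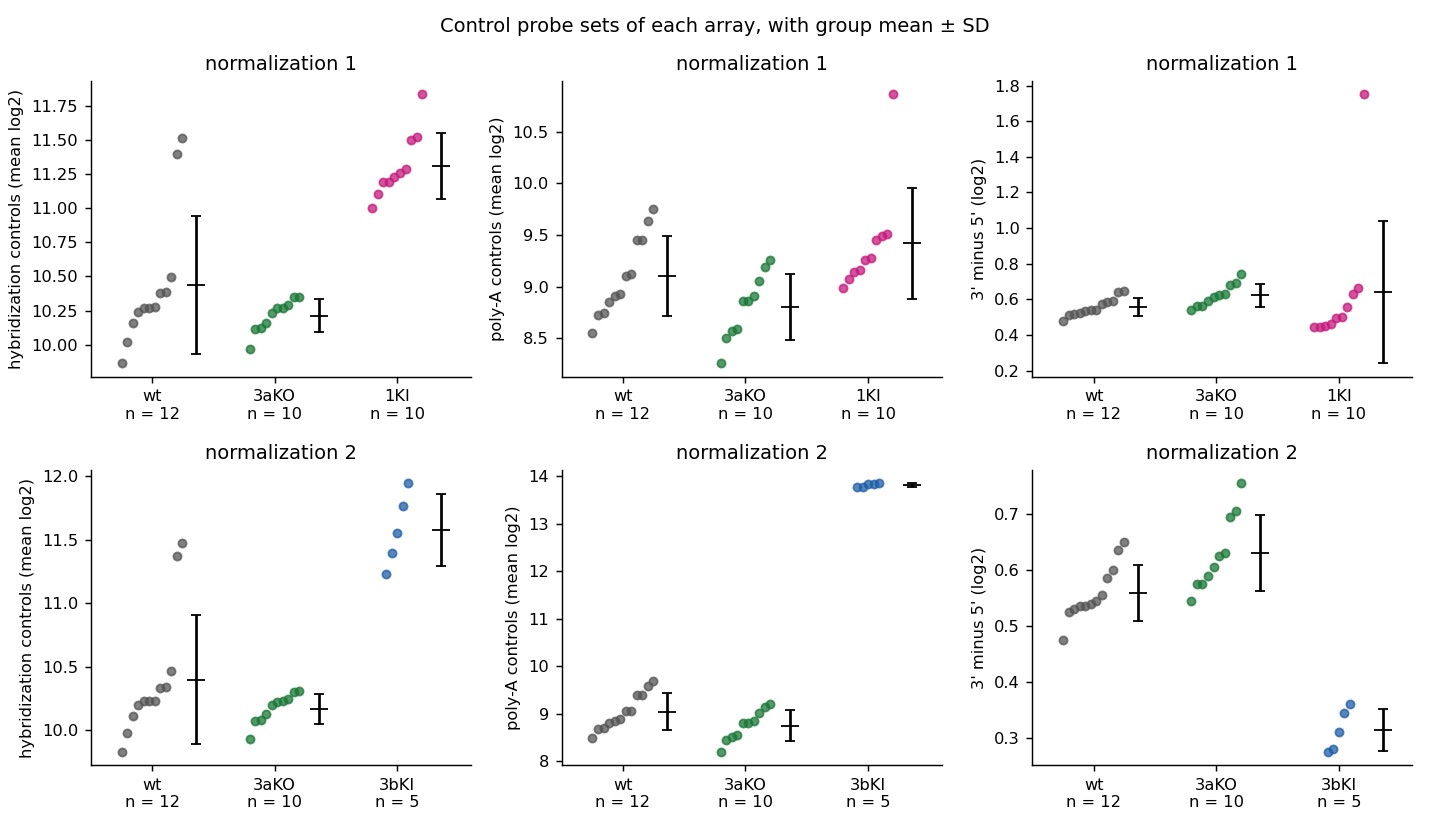
Mean log2 signal of the hybridization controls and of the poly-A controls, and the 3' minus 5' difference of Gapdh and Actb (log2), for each array of both normalizations, 1 point per array, grouped by genotype. All 10 1KI arrays have hybridization control levels between 11.0 and 11.8 and all 5 3bKI arrays have poly-A control levels of 13.8, while the wt and 3aKO arrays normalized with 3bKI have poly-A levels between 8.19 and 9.70.

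Of the altered genes themselves, E2f3 had a log2 change of -0.25 ± 0.07 (SE, adjusted p = 0.13, n = 10 and 12) in 3aKO at the brighter of its probe sets. It lay below the wt level of 8.00 ± 0.18 (SD) in 10 of 10 arrays without passing. The dimmer E2f3 probe set had a change of -0.17 ± 0.06. In 3bKI (5 arrays) against 3aKO, the dimmer probe set rose by 0.40 ± 0.08 (adjusted p = 3.6e-04), whereas the brighter had a change of -0.02 ± 0.10. None of 3 probe sets for E2f1 passed in 1KI against wt, with log2 changes of -0.25, -0.19 and -0.10, and whether they cover the inserted sequence is not given in the sources used here. In the comparisons with wt, E2f2 passed in 3bKI with a rise of 0.29 ± 0.11 (adjusted p = 0.043), and the brighter E2f3 probe set fell there by 0.24 ± 0.09 (adjusted p = 0.049), a call that ended with the hybridization control level as a block (-0.03). The dimmer E2f3 probe set had a change of the opposite sign there (0.20 ± 0.08) without passing. Both calls are near the threshold: they ended in 10 and 11 of the 17 fits that left out 1 array, with changes from 0.15 to 0.41 for E2f2 and from -0.30 to -0.16 for E2f3. Over all alternatives E2f2 passed in 11 of 32, with a lowest change of 0.03 (RNA integrity as a covariate), and E2f3 in 12 of 33.

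**Figure D2:**
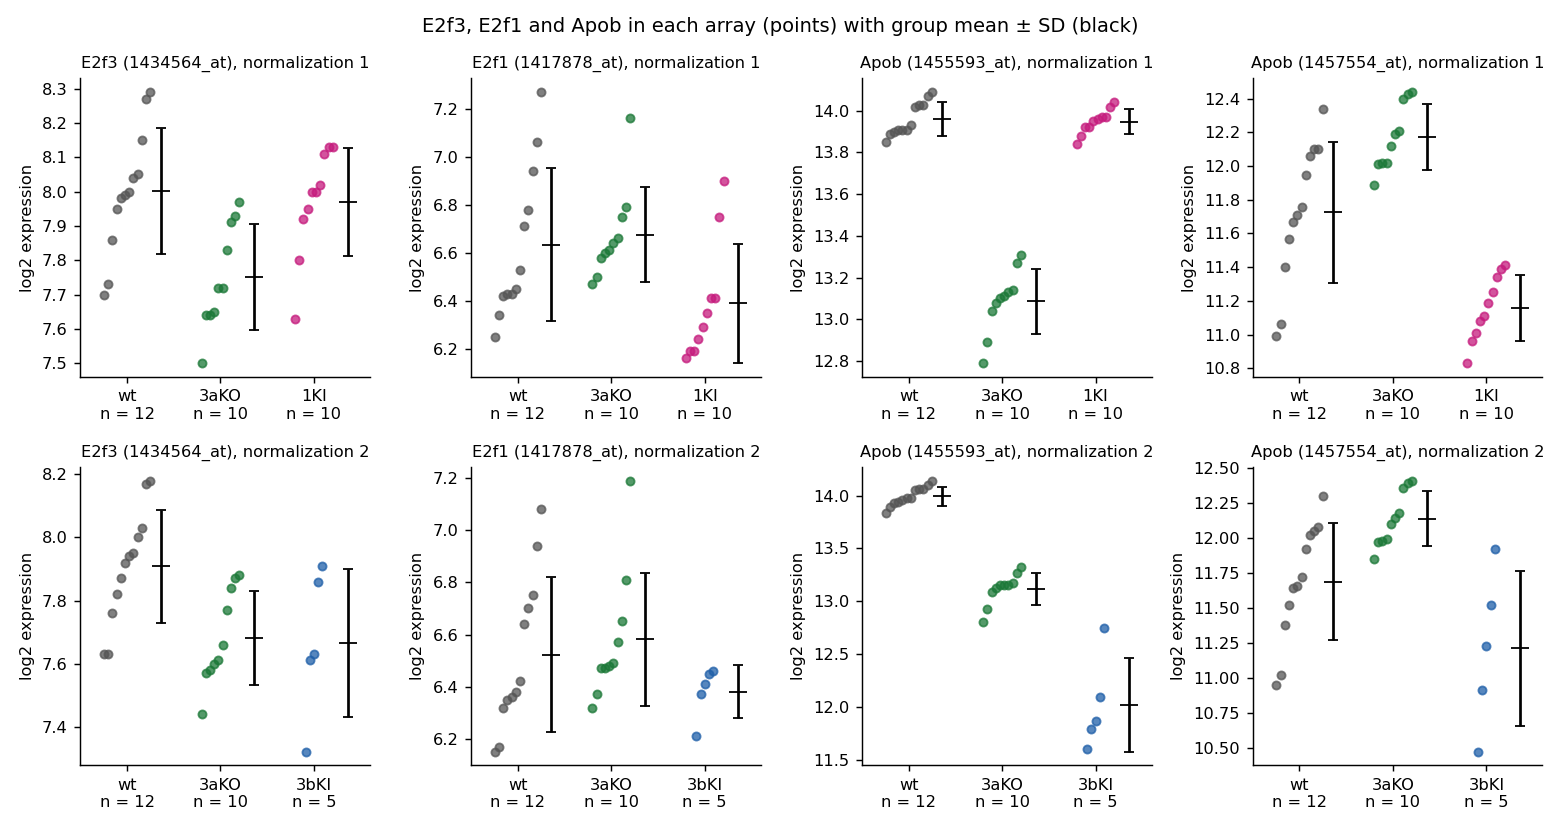
Log2 signal of E2f3 and E2f1 (brightest probe set each) and of both Apob probe sets in each array of both normalizations, 1 point per array, with the mean and SD of each genotype. At the brighter Apob probe set the 3bKI arrays average 12.02 and the wt arrays 13.99, and at the dimmer 11.21 and 11.69.

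In livers without E2f3a, Ppargc1a, which encodes a coactivator of mitochondrial and gluconeogenic genes, rose by 1.12 ± 0.16 (log2 change ± SE, adjusted p = 3.0e-04, n = 10 and 12), from 7.38 ± 0.42 to 8.50 ± 0.38 (SD), in 10 of 10 arrays. Mme, the gene of the membrane peptidase neprilysin, rose by 1.06 ± 0.20 (adjusted p = 0.012), and Kdm5a, which encodes a histone demethylase, by 0.62 ± 0.09 (adjusted p = 3.0e-04). Smaller rises, from 0.43 to 0.59, were called for Celf2, Septin10, Dcaf12l1, Gprin3, Col4a5, Zfp800 and Scaf11, each in 10 of 10 arrays. Among lipid genes, Apob, which encodes the structural protein of very-low-density lipoprotein, fell by 0.88 ± 0.05 (adjusted p = 9.2e-15, 10 of 10 arrays). The fatty acid desaturase gene Scd1 fell by 0.44 ± 0.10 (adjusted p = 0.040, 9 of 10 arrays). The sulfurtransferase gene Mpst fell by 0.66 ± 0.13 (adjusted p = 0.023), and Raly, Tlx2, Kdelr1, Necab2 and Rflna fell as well, with changes between -0.39 and -0.20. In all, 20 genes rose and 12 fell, 7 of them by more than 1.5-fold, and 2166 of the 18193 genes had an unadjusted p under 0.05. Leaving out 1 array gave 16 to 56 called genes, and array weights 307, of which 148 were higher and 159 lower. E2f1 (0.04), E2f2 (0.01), Ccne1 (0.08), Cdc6 (-0.04), Mcm6 (0.25), Cdkn1a (-0.10) and Afp (0.06) did not pass.

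In 3aKO against wt, 3 gene lists passed, all toward higher values, although none of their members passed singly. Among 24 interferon-stimulated genes (median log2 change 0.15, adjusted p = 0.0059), 0 rose and 0 fell, and 0 did so when adjusted over the list alone. For 6 of them limma gave an unadjusted p under 0.05, all higher, led by Ifit3 (0.29 ± 0.10) and Ifit1 (0.40 ± 0.15). The 40 G1/S and DNA replication genes (median 0.10, adjusted p = 0.042) and the 17 macrophage and Kupffer cell markers (median 0.14, adjusted p = 0.044) likewise had 0 called members, and 0 when adjusted over the list alone. By limma 1 member of each had an unadjusted p under 0.05, Tyms (0.23 ± 0.08) and Csf1r (0.22 ± 0.11). With an estimated correlation between genes, each of the 3 lists had adjusted p = 1.00. Within the arrays of the lower hybridization control level, or with that level as a block, the mean log2 changes of the interferon, G1/S and macrophage lists were 0.15, 0.04 and 0.11, and the call of the interferon list alone was kept. The call of Apob rests on the brighter of its probe sets, since the dimmer had a change of 0.45 ± 0.12 and the mean of both one of -0.21, neither passing. With the level as a block 15 genes passed, all among the 32, and with a sex index beside the block 17. The fatty acid synthesis list (-0.13) passed with the block. Of 18 named calls, 10 were kept with the block, 11 with block and sex index, and 9 with the probe sets of each gene averaged, which also ended the calls of Ppargc1a (0.55), Kdm5a (0.18) and Scd1 (-0.75), while Celf2 (0.27) kept its call.

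In livers with the E2F1 knock-in, Pctp, which encodes phosphatidylcholine transfer protein, rose over wt by 2.67 ± 0.30 (log2 change ± SE, adjusted p = 4.3e-08, n = 10 and 12) in 10 of 10 arrays. Echdc3, an enoyl-CoA hydratase domain gene, rose by 2.38 ± 0.12 (adjusted p = 9.0e-16) and the phospholipid transfer protein gene Pltp by 1.40 ± 0.16 (adjusted p = 1.1e-07), also in 10 of 10 arrays. Gdpd3, a glycerophosphodiester phosphodiesterase domain gene, fell by 4.92 ± 0.47 (adjusted p = 3.1e-09), from 10.34 ± 1.60 to 5.41 ± 1.11 (SD). The cell cycle inhibitor gene Cdkn1a rose by 0.81 ± 0.19 (adjusted p = 0.0016, 9 of 10 arrays). Erdr1 (2.80 ± 0.16), BC023105 (1.98 ± 0.36), Arrdc2 (1.67 ± 0.19), Itih5 (1.56 ± 0.13), the nuclear RNA Neat1 (1.51 ± 0.29) and the protease gene Ctse (1.44 ± 0.20) rose in 10 of 10 arrays. Akr1e1 (-1.61 ± 0.22), Hddc3 (-1.59 ± 0.27), Psmc3ip (-1.54 ± 0.22), Dnaic1 (-1.51 ± 0.23), Adat2 (-1.42 ± 0.10), Cyp2g1 (-1.38 ± 0.22), Tmem242 (-1.35 ± 0.07) and 1700001C19Rik (-1.34 ± 0.20) fell. Of 5026 called genes, 1850 rose and 3176 fell, 422 by more than 1.5-fold and 86 by more than 2-fold. With equal array medians 1578 were higher and 4321 lower, and with the hybridization control level as a block 388 and 394. The E2F target genes Ccne1 (-0.09), Cdc6 (-0.36) and Mcm6 (-0.98 ± 0.40, adjusted p = 0.066) did not pass, nor did E2f3 (-0.03), E2f2 (-0.09) or Afp (-0.26).

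Of 27 acute phase genes, 10 rose, 2 fell and 15 did not pass in 1KI against wt (12 rose and 2 fell when adjusted over the list alone; median log2 change 0.15, mean 0.26, list adjusted p = 0.0068). With an estimated correlation the list had adjusted p = 1.00. Lcn2, which encodes an iron-binding acute phase protein, rose by 1.66 ± 0.45 (adjusted p = 0.0064, 8 of 10 arrays). Saa1 rose by 1.11, the interleukin 6 receptor gene Il6ra by 0.65 ± 0.14, Socs3 by 0.58, Lbp by 0.47, Cebpd by 0.44 and Saa4 by 0.32 ± 0.09. The hepcidin gene Hamp2 fell by 1.94 ± 0.29 (adjusted p = 5.3e-06, 9 of 10 arrays) and Apcs fell by 0.42. The 40 G1/S genes (0 rose, 9 fell, 0 and 6 adjusted over the list alone, mean -0.31, adjusted p = 0.055) and the 17 hepatocyte markers (1 rose, 0 fell, 1 and 0 adjusted over the list alone, mean 0.02, adjusted p = 0.55) did not pass. All 1KI arrays had the higher hybridization control level, so that a fit with the level as a block gives the same changes as one within that level (10 against 2 wt arrays). The acute phase list kept its call there with a mean of 0.30, the cholesterol synthesis (0.46), fatty acid synthesis (0.23) and endothelial (0.16) lists passed as well, and 782 genes passed with the block (639 of them among the 5026) and 174 within the level alone. With the block 14 of 23 named calls were kept, among them Echdc3 (2.54), Pctp (2.78), Erdr1 (3.04) and Gdpd3 (-5.43), and not Lcn2 (1.88), Cdkn1a (0.98), Hamp2 (-1.52), Ctse (0.84) or Dnaic1 (-0.78). With a sex index beside the block 672 genes passed, 16 of 23 named calls were kept, Hamp2 (-1.86) among them, and the acute phase list kept its call with a mean of 0.18. Without probe sets of the less specific _x_at kind, Erdr1 had a change of 0.17 and Hamp2 one of -0.16, neither passing, and with the probe sets of each gene averaged Erdr1 stood at 1.48, Neat1 at 0.77, Ctse at 0.54, Hamp2 at -1.05, Hddc3 at -0.86 and Tmem242 at -0.47, all still called. Neat1 was also called with the block (2.37).

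**Figure D3:**
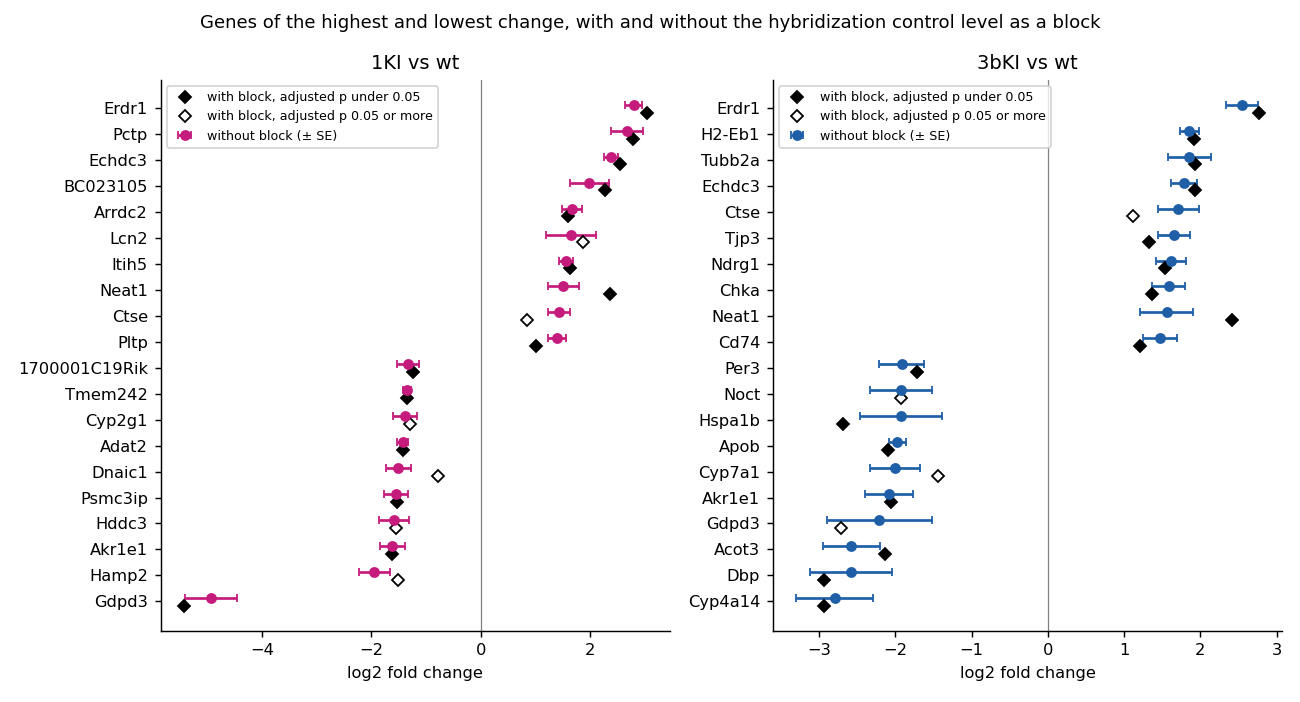
Log2 change against wt of the named genes in 1KI (10 against 12 arrays) and 3bKI (5 against 12 arrays): circles with SE without, and diamonds with, the hybridization control level as a block, filled where the adjusted p is under 0.05. In 1KI, Gdpd3 lies at -4.92 and Erdr1 at 2.80, and in 3bKI, Cyp4a14 lies at -2.80 and Erdr1 at 2.55.

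Against 3aKO, Pola1, the catalytic subunit gene of DNA polymerase alpha, fell in 1KI livers by 1.13 ± 0.11 (log2 change ± SE, adjusted p = 3.5e-09, n = 10 and 10, 10 of 10 arrays), and the clamp loader gene Rfc3 by 0.77 ± 0.16 (adjusted p = 2.7e-04). Ube2c, which encodes a ubiquitin-conjugating enzyme of mitosis, fell by 0.88 ± 0.23 (adjusted p = 0.0030) and the spindle checkpoint gene Mad2l1 by 0.80 ± 0.21 (adjusted p = 0.0032). Mcm6 fell by 1.23 ± 0.42 (adjusted p = 0.023) and E2f1 by 0.29 ± 0.11 (adjusted p = 0.049) at the brightest of its probe sets, while E2f3 rose by 0.22 ± 0.07 (adjusted p = 0.022) and Cdkn1a by 0.92 ± 0.20 (adjusted p = 6.0e-04). The other E2f1 probe sets had changes of -0.14 and -0.08 without passing, and the call of E2f1 held in 8 of 14 alternatives, with changes from -0.32 to -0.17. Mlxipl, which encodes the carbohydrate response factor ChREBP, rose by 1.45 ± 0.13 (adjusted p = 8.0e-10), from 10.69 ± 0.17 to 12.13 ± 0.32 (SD), and Igfbp1 by 1.46 ± 0.41 (adjusted p = 0.0067, 9 of 10 arrays). As against wt, Erdr1 (2.98), Pctp (2.86), Echdc3 (2.28), Ctse (1.61), Pltp (1.55), Arrdc2 (1.48), Itih5 (1.43) and BC023105 (1.42) rose. Gdpd3 (-5.29), Hamp2 (-2.18), Hddc3 (-1.66), Cyp2g1 (-1.62), Akr1e1 (-1.60), Psmc3ip (-1.56), Meiob (-1.43), Vldlr (-1.42), 1700001C19Rik (-1.40) and Tmem242 (-1.39) fell. Without _x_at probe sets Erdr1 (0.15) and Hamp2 (-0.12) did not pass, and Vldlr (-1.03) did. With the probe sets of each gene averaged Erdr1 stood at 1.56, Ctse at 0.65, Hamp2 at -1.15, Hddc3 at -0.89, Pola1 at -0.54 and Tmem242 at -0.42, all still called. Of 5636 called genes, 2174 rose and 3462 fell. With equal array medians 1731 were higher and 4494 lower, and with the level block 215 and 202. Ccne1 (-0.17), Cdc6 (-0.32) and E2f2 (-0.11) did not pass.

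Of 40 G1/S and DNA replication genes, 0 rose, 15 fell and 25 did not pass in 1KI against 3aKO (0 and 16 adjusted over the list alone; median log2 change -0.37, adjusted p = 0.0068). Of 30 G2/M and mitosis genes, 0 rose, 8 fell and 22 did not pass (0 and 8 adjusted over the list alone; median -0.43, adjusted p = 0.024). Of 27 acute phase genes, 8 rose, 2 fell and 17 did not pass (8 and 2 adjusted over the list alone; median 0.17, adjusted p = 0.041). Il6ra rose by 0.78 ± 0.15, Cebpd by 0.47 ± 0.13 and Fga, a fibrinogen chain gene, by 0.16 ± 0.04. With an estimated correlation each of these 3 lists had adjusted p = 1.00. In the same comparison, of 17 macrophage markers 0 rose and 6 fell (0 and 6 adjusted over the list alone, mean -0.28, list adjusted p = 0.17), and of 18 lymphocyte markers 1 rose and 6 fell (1 and 6 adjusted over the list alone, mean -0.15, list adjusted p = 0.56). Of 24 interferon-stimulated genes 2 rose and 12 fell (2 and 14 adjusted over the list alone, mean -0.29, list adjusted p = 0.051). No level of the hybridization controls holds both 1KI and 3aKO arrays, so that the block links them through wt: with it 417 genes passed, 360 of them among the 5636, and 11 of 36 named calls were kept. The G1/S list then had a mean of -0.08 in place of -0.41 with an upward test direction, and the G2/M list a mean of -0.26 in place of -0.41, neither passing. Pola1 (-0.96), Mlxipl (1.67) and the acute phase list (0.32) kept their calls, the cholesterol synthesis (0.48), fatty acid synthesis (0.37), endothelial (0.26) and interferon (-0.37) lists passed as well, and Rfc3 (-0.36), Mcm6 (-0.38), Ube2c (-0.95), Mad2l1 (-0.49), Igfbp1 (2.06) and Cdkn1a (1.12) did not. Fga turned to -0.01 without passing. With a sex index beside the block 391 genes passed, 13 of 36 named calls were kept, and the G1/S and G2/M lists had means of -0.03 and -0.14.

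In livers with the E2F3b knock-in, Cyp4a14, a fatty acid omega-hydroxylase gene driven by PPAR alpha, fell from wt by 2.80 ± 0.51 (log2 change ± SE, limma adjusted p = 8.8e-05, n = 5 and 12), from 11.38 ± 0.80 to 8.59 ± 1.27 (SD), in 5 of 5 arrays. The vanin gene Vnn1 fell by 1.81 ± 0.26 (adjusted p = 3.6e-06), the thioesterase gene Acot3 by 2.58 ± 0.37 (adjusted p = 4.9e-06). Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, fell by 2.01 ± 0.33 (adjusted p = 2.3e-05, 5 of 5 arrays). The clock output gene Dbp fell by 2.58 ± 0.54 (adjusted p = 4.6e-04), Per3 by 1.91 ± 0.29 and Wee1 by 1.67 ± 0.17 (adjusted p = 2.7e-08). Apob fell by 1.97 ± 0.11 (adjusted p = 2.4e-13, 5 of 5 arrays), Akr1e1 by 2.08 ± 0.31, Hspa1b by 1.93 ± 0.53 and Noct by 1.92 ± 0.41. Gdpd3 fell by 2.21 ± 0.69 (adjusted p = 0.015, 4 of 5 arrays), and without 3bKI replicate 5 its change was -1.40 and did not pass. The MHC class II genes H2-Eb1 and Cd74 rose by 1.86 ± 0.12 (adjusted p = 1.8e-11) and 1.47 ± 0.22 (adjusted p = 7.2e-06), and Cdkn1a by 1.06 ± 0.24 (adjusted p = 0.0011, 4 of 5 arrays). Erdr1 (2.55 ± 0.22), Tubb2a (1.85 ± 0.28), Echdc3 (1.78 ± 0.17), Ctse (1.71 ± 0.26), Tjp3 (1.66 ± 0.21), Ndrg1 (1.62 ± 0.20), Chka (1.58 ± 0.21) and Neat1 (1.56 ± 0.34) rose as well. Of 5318 called genes, 2433 rose and 2885 fell, 871 by more than 1.5-fold and 135 by more than 2-fold. With equal array medians 1742 were higher and 3693 lower, and with the hybridization control level as a block 602 and 981. Ccne1 (-0.17), Cdc6 (-0.61), Mcm6 (-0.82), E2f1 (-0.14) and Afp (0.08) did not pass.

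Of 22 fatty acid oxidation and PPAR alpha genes, 1 rose, 14 fell and 7 did not pass in 3bKI against wt (1 and 15 adjusted over the list alone; median log2 change -0.30, adjusted p = 6.3e-04). Acaa1b (-0.56 ± 0.08), Decr1 (-0.45 ± 0.07) and Acadvl (-0.31 ± 0.05) were among those that fell, and Pdk4 rose by 1.12. Of 19 clock genes, 4 rose, 10 fell and 5 did not pass (5 and 11 adjusted over the list alone; median -0.67, adjusted p = 0.025). Usp2 (-1.73 ± 0.24), Per2 (-1.50 ± 0.21) and Hlf (-0.68 ± 0.09) fell, and Nfil3 (0.66), Clock (0.43), Arntl (0.40) and Npas2 (0.37) rose. Of 14 heat shock genes, 1 rose, 10 fell and 3 did not pass (1 and 11 adjusted over the list alone; median -0.34, adjusted p = 0.015). Chordc1 (-0.59 ± 0.14), Hspe1 (-0.34 ± 0.07), Dnaja1 (-0.34 ± 0.09) and the mitochondrial chaperone gene Hspd1 (-0.24 ± 0.04) fell. Of 24 interferon-stimulated genes, 8 rose, 0 fell and 16 did not pass (9 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.024). Stat2 rose by 1.00 ± 0.09, Tap1 by 0.97 ± 0.18, Irf7 by 0.63 ± 0.15 and Dhx58 by 0.62 ± 0.12. With an estimated correlation each of these 4 lists had adjusted p = 1.00. Of 17 bile acid genes 4 rose, 3 fell and 10 did not pass (4 and 4 adjusted over the list alone; list adjusted p = 0.98). Cyp7a1 fell while Nr0b2 (0.96), Cyp8b1 (0.75), Hsd3b7 (0.74) and Cyp27a1 (0.41) rose. With the hybridization control level as a block, which compares 3bKI with the 2 wt arrays of its level, 1583 genes passed (1430 of them among the 5318), and 133 passed within that level alone. The 4 lists kept their calls with the block, with means of -0.41, -0.72, -0.72 and 0.21, and within the level the clock list alone did not. The endothelial (0.33) and cholesterol synthesis (0.34) lists passed with the block as well. Without it 4 of 15 endothelial markers rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone, mean 0.20, list adjusted p = 0.081). With the block 26 of 39 named calls were kept, but not those of Cyp7a1 (-1.43), Gdpd3 (-2.71), Ctse (1.12), Tap1 (0.77), Irf7 (0.23) or E2f3. With a sex index beside the block 1482 genes passed, 26 of 39 named calls were kept, Cyp7a1 (-1.68) among them, and the interferon list (0.11) lost its call. With RNA integrity as a covariate, whose values in 3bKI (0.275 to 0.360) and wt (0.475 to 0.650) do not overlap, 605 genes passed, 589 of them among the 5318, and 97.7% of the 5318 kept their direction with a median ratio of 0.90. Both fits use the same arrays, so agreement in direction is partly built in. Of the named calls, 12 of 39 were kept, including Cyp4a14 (-4.92), Apob (-1.76), H2-Eb1 (1.49), Echdc3 (2.09), Vnn1 (-2.34), Wee1 (-1.64) and Stat2 (0.71). Dbp (-1.60), Cyp7a1 (-1.06), Cd74 (0.94) and Cdkn1a (0.39) no longer passed, and of the 4 lists the fatty acid oxidation list (-0.64) kept its call. The clock (-0.48), heat shock (-0.44) and interferon (0.02) lists lost theirs, from means of -0.66, -0.52 and 0.28, and the G1/S (-0.58) and G2/M (-0.57) lists passed instead. Erdr1 had a change of 0.08 without _x_at probe sets. With the probe sets of each gene averaged Erdr1 stood at 1.31, Neat1 at 0.84, Ctse at 0.78, Tap1 at 0.29, Dhx58 at 0.40, Akr1e1 at -1.28, Apob at -1.22, Per3 at -0.80 and Per2 at -0.71, all still called.

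**Figure D4:**
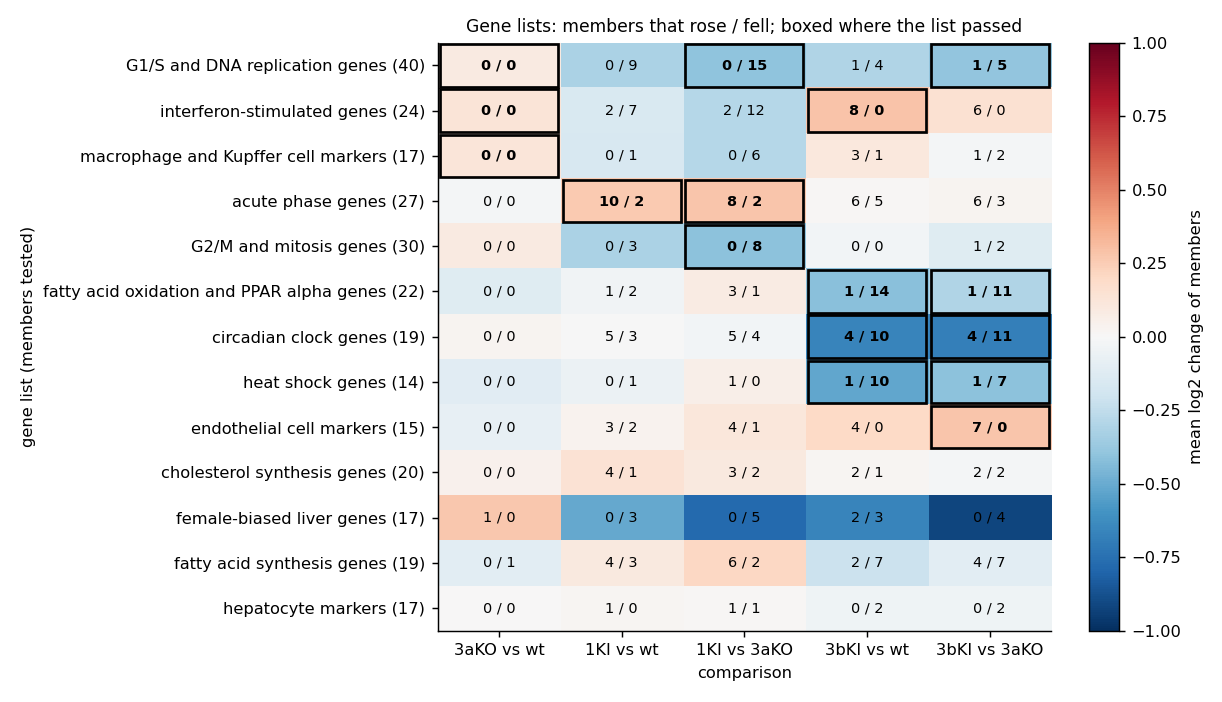
Mean log2 change of the members of 13 gene lists (rows) in the 5 comparisons (columns), as colour, with the numbers of members that rose / fell, boxed where the list test passed at an adjusted p under 0.05 with the preset correlation. Fatty acid oxidation genes have 1 / 14 in 3bKI against wt and 1 / 2 in 1KI against wt.

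Mme, higher in 3aKO than in wt, was lower in 3bKI: against 3aKO it fell by 2.01 ± 0.27 (log2 change ± SE, limma adjusted p = 1.4e-06, n = 5 and 10), in 5 of 5 arrays. Pola1 fell by 0.97 ± 0.13 (adjusted p = 1.9e-06, 5 of 5 arrays). Cpt1a, which encodes the enzyme that admits fatty acids to mitochondria, fell by 0.50 ± 0.08 (adjusted p = 1.9e-05), Vnn1 by 1.53 ± 0.26, Cyp4a14 by 2.34 ± 0.52 and Hao2 by 1.99 ± 0.53 (adjusted p = 0.0042, 4 of 5 arrays). Dbp (-2.90 ± 0.56), Noct (-2.24), Per3 (-1.99), Usp2 (-1.93), Wee1 (-1.60) and Hlf (-0.79) fell, as did Gdpd3 (-2.58), Akr1e1 (-2.08) and Acot3 (-1.85). Erdr1 (2.72), Ctse (1.88), H2-Eb1 (1.82 ± 0.13, adjusted p = 3.7e-11), Tubb2a (1.75), Echdc3 (1.70), Chka (1.60), Tjp3 (1.56), Ndrg1 (1.51), Yae1d1 (1.51), the aminopeptidase gene Anpep (1.51 ± 0.20) and Cdkn1a (1.14 ± 0.25) rose. Of 6218 called genes, 3002 rose and 3216 fell. With equal array medians 2006 were higher and 4042 lower, and with the level block 435 and 797. E2f2 (0.29), Ccne1 (-0.27), Mcm6 (-1.09), Cdc6 (-0.60), E2f1 (-0.20) and Afp (0.01) did not pass.

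In 3bKI against 3aKO, 5 lists passed. Of 40 G1/S genes 1 rose, 5 fell and 34 did not pass (1 and 5 adjusted over the list alone; median log2 change -0.37, adjusted p = 0.028), among them Ccne2 (-1.10 ± 0.24), Chaf1b (-0.75 ± 0.15) and Mybl2 (0.28 ± 0.07). Of 22 fatty acid oxidation genes 1 rose, 11 fell and 10 did not pass (1 and 12 adjusted over the list alone; median -0.26, adjusted p = 0.015), with Acaa1b (-0.47 ± 0.08) and Slc25a20 (-0.41 ± 0.07). Of 19 clock genes 4 rose, 11 fell and 4 did not pass (5 and 11 adjusted over the list alone; median -0.79, adjusted p = 0.032). Of 14 heat shock genes, 1 rose, 7 fell and 6 did not pass (1 and 10 adjusted over the list alone; median -0.36, adjusted p = 0.044). Dnaja1 (-0.38 ± 0.09), Hspe1 (-0.34 ± 0.07) and Hspd1 (-0.24 ± 0.05) fell and Hspb1 (0.55 ± 0.13) rose. Of 15 endothelial cell markers 7 rose, 0 fell and 8 did not pass (7 and 1 adjusted over the list alone; median 0.25, adjusted p = 0.044). Dnase1l3 (0.87 ± 0.13), Pecam1 (0.60 ± 0.13), Gpr182 (0.56 ± 0.13) and Egfl7 (0.44 ± 0.09) rose. With an estimated correlation each of the 5 lists had adjusted p = 1.00. No hybridization control level holds arrays of both groups, and with the level as a block 1232 genes passed and 18 of 39 named calls were kept. The G1/S list then had a mean of -0.07 and an upward test direction without passing, and Anpep a change of 0.33, while the other 4 lists kept their calls (-0.29, -0.75, -0.66 and 0.43) and the cholesterol synthesis list (0.36) passed. With a sex index beside the block 1264 genes passed, 18 of 39 named calls were kept, and the fatty acid oxidation list (-0.28) lost its call as well. With RNA integrity as a covariate 116 genes passed and 6 of 39 named calls were kept. The G1/S (-0.75) and fatty acid oxidation (-0.58) lists kept their calls, and the G2/M (-0.82) and female-biased (-1.36) lists passed as well. The clock (-0.45) and heat shock (-0.31) lists lost their calls, and the endothelial list turned to a mean of -0.12, with Pecam1 at -0.04 and Gpr182 at -0.07. Erdr1 had a change of 0.07 without _x_at probe sets. With the probe sets of each gene averaged it stood at 1.40, Ctse at 0.88, Yae1d1 at 0.34, Akr1e1 at -1.32, Cpt1a at -0.97, Per3 at -0.83, Pola1 at -0.42, Chaf1b at -0.39 and Hspe1 at -0.19, all still called.

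Whether the knock-in livers resemble the knock-out was asked with a score over 100 genes chosen in odd-numbered 3aKO and wt arrays and measured in the others, on which wt averages 0 and 3aKO 1. The 10 1KI arrays averaged 0.40 ± 0.59 (SD, from -0.17 to 1.91), and their difference passed neither from 3aKO (permutation test, adjusted p = 0.16) nor from wt (adjusted p = 0.23). Without 1KI replicate 6 they averaged 0.24 and lay below 3aKO (exact permutation p = 0.0020). With other numbers or choices of genes, or the sex index regressed out, they lay below 3aKO in 5 of 5 alternatives (permutation p from 3.3e-04 to 0.038), at -0.15 with the even-numbered arrays choosing. The 5 3bKI arrays averaged -0.22 ± 0.36 (from -0.67 to 0.22), below 3aKO (exact permutation test, adjusted p = 0.032), with no difference from wt that passed (adjusted p = 0.41). With the even-numbered arrays choosing the genes their mean was 0.37, on the other side of wt. All knock-in arrays had the higher hybridization control level and all 3aKO arrays the lower, and the score was not repeated with the level. Wt replicate 2, the only even-numbered wt array at the higher level, had the lowest wt score in both normalizations (-0.67 and -0.65). The distance of the knock-ins from 3aKO can thus not be told apart from the level. Of the genes called in 3aKO against wt, 1 rose and 2 fell in both 3aKO and 1KI (2.03 and 2.09 for independent lists), and Col4a5, Mtpn and Srp72 rose in 3aKO and fell in 1KI. In the normalization with 3bKI, 11 rose and 7 fell in both 3aKO and 3bKI (4.01 and 1.90 for independent lists), and 8 went opposite ways. Lists of comparisons that share the wt arrays are not independent. Simulated data without effects gave 0 in both, but by construction next to no gene is called there. They therefore cannot say how much overlap the shared wt arrays add. With odd-numbered wt arrays for 3aKO and even-numbered ones for the knock-in, 3 rose and 1 fell in both 3aKO and 3bKI, and the other way round 2 and 1, and for 1KI 0 and 0, and 1 and 0. Across all genes, which are not independent replicates, the changes against the shared wt arrays had a correlation of 0.002 for 3aKO and 1KI and of -0.058 for 3aKO and 3bKI. Simulated data with shared wt arrays alone had 0.461 and 0.366 on average. The covariances were 4.6e-05 and -0.0016, and 0.0037 and 0.0035 in the simulated data. Erdr1, Echdc3, Ctse, Neat1 and Cdkn1a were higher and Gdpd3 and Akr1e1 lower than wt in both knock-ins, and whether their changes differ between the knock-ins was not tested. Both knock-ins had the higher hybridization control level and were compared with the same wt arrays, which could by itself give changes in common. With the level as a block Echdc3 kept its call in 1KI (2.54) and 3bKI (1.93), and Ctse in neither. Cdkn1a lost its call with the block in 1KI, and Gdpd3 lost its call in 3bKI but not in 1KI. The rise of Erdr1 rests on an _x_at probe set in both knock-ins and was small without it. Genes within 20 Mb of E2f3 in the GRCm38.p6 annotation were called less often than the others in 1KI against 3aKO (52 of 244, odds ratio 0.597, Fisher's exact p = 7.9e-04, adjusted p = 0.0040), and in the other 4 comparisons no difference passed.

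**Figure D5:**
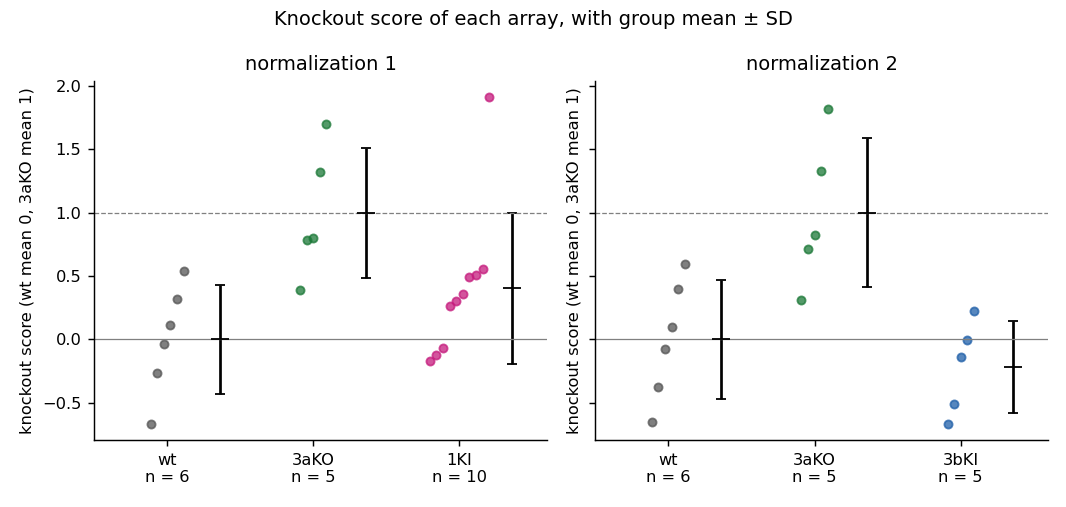
Knockout score of each array (unitless; wt mean 0, 3aKO mean 1) for even-numbered wt and 3aKO arrays and all knock-in arrays, 1 point per array, with mean and SD. The 10 1KI arrays lie between -0.17 and 1.91 and the 5 3bKI arrays between -0.67 and 0.22.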

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

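The test of the poly-A controls and the fits with the hybridization control level were chosen only after the control signals had been seen. Among 93 groups of 4 to 10 arrays searched for an array far from its group, 7 had one, and chance flags about 1 in 20 groups, or 4.65 of 93.

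1KI replicate 6 stood apart in its control signals. Its 3' minus 5' difference was 1.75, against 0.445 to 0.665 in the other 1KI arrays (gap over range 0.831), its poly-A control level was 10.9 against 8.99 to 9.51 (0.719), and its knockout score was 1.91 against -0.17 to 0.56 (0.648). Among genes, 1KI replicate 3 had a BC023105 signal of 11.50 against 6.94 to 9.28 in the others (0.487). 1KI replicate 1 had Hamp2 at 13.16 against 9.89 to 11.60 (0.477) and Il6ra at 9.35 against 10.40 to 11.26 (0.550), so that its hepcidin and interleukin 6 receptor genes lay toward the wt side. 3bKI replicate 3 had Hspe1 at 12.39 against 12.18 to 12.24 (0.714).

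Signals outside the measured liver genes also differed between genotypes. The hybridization controls were higher in 1KI than in wt by 0.872 (permutation test, adjusted p = 9.7e-04) and in 3bKI than in wt by 1.18 (adjusted p = 0.0026), and the poly-A controls were higher in 3bKI than in wt by 4.77 (adjusted p = 9.7e-04).

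The first pattern is the 5026 genes called in 1KI against wt. Against a lower RNA quality of the 1KI arrays stand the 4852 genes called without 1KI replicate 6. The other 1KI arrays had 3' minus 5' differences of 0.445 to 0.665, next to 0.480 to 0.645 in wt. With RNA integrity as a covariate 5239 genes were called, but the slope of that fit rests largely on 1KI replicate 6, so this count does not decide. Hybridization of the 1KI arrays apart from the others stays open. The 2 wt arrays at the 1KI level lay at 0.281 (SD 0.034) on a scale from the other wt arrays (0) to 1KI (1). This is below the 0.5 set in advance for this cause, and the highest of the other wt arrays stood at 0.236. The genes of the scale were chosen with the other wt arrays and without these 2, which alone can place the 2 above 0. The positions are thus not alike, and 2 arrays, both with Y-linked signal, are too few to decide. Other strain segments in the 1KI mice also stay open, since of the 100 genes with the smallest p 39 lay within 2 Mb of another, against a median of 23 and a highest of 37 in 100 random draws, which neighbours regulated together could give as well. An effect of the E2F1 knock-in itself remains among the open explanations, and the design does not separate it from the strain of its carriers.

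The second pattern is the 5318 genes called in 3bKI against wt. Against other strain segments in the 3bKI mice stands a number of 20 of the 100 top genes near another, which lay below the median of 23 in random draws by less than their spread (SD 5.84), too little to exclude it. Labelling of the 3bKI arrays apart from the others cannot be told apart from the genotype, since 5 of 5 3bKI arrays had poly-A levels outside the range of all wt and 3aKO arrays. Livers taken at another time of day could account for the clock genes: those that peak with Arntl averaged 0.24 ± 0.52 (SD over 5 genes, 4 rose) and those that peak with Dbp -1.14 ± 0.94 (SD over 10 genes, 8 fell), 1.37 apart, although a change in the clock by the knock-in would look alike. An effect of the E2F3b knock-in itself stays open as well and was not tested apart from these.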

How the results depend on the processing

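The hybridization control level as a block, alone or with a sex index, its arrays alone, leaving out its wt arrays, the average of similar wt arrays, and, for gene lists, RNA integrity as a covariate and leaving out 1KI replicate 6 were chosen only after the data were seen. For the named genes, the side of the threshold held, with no called gene turning, in 537 of 602 values (gene by alternative) in 3aKO against wt. In 1KI it held in 434 of 476 against wt and 519 of 579 against 3aKO. In 3bKI it held in 1320 of 1448 (wt) and 1274 of 1373 (3aKO). Of these, 3, 8, 3, 9 and 22 are of genes that changed sign without passing in either fit. Fits without 1 array, which seldom changed a call, count in 3bKI alone and raise its shares. Where no reason is given, the cause was not tested.

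With all probe sets in place of 1 per gene, more tests by construction, 129, 13132, 14099, 12481 and 14151 passed in the same 5 comparisons. In 3aKO against wt (32 genes) array weights gave 307, the level block 15, with a sex index beside it 17, leaving out the wt arrays of the higher level 15, and averaging similar wt arrays 19. Averaged were wt replicates 8 and 9 (SD of difference 0.171) and 1 and 2 (0.191), against a median of 0.283 within groups. Wt replicates 1 and 8, of unlike level, had 0.192. Leaving out 1 array gave 16 genes (3aKO replicate 3) to 56 (3aKO replicate 10), with 17 for 3aKO replicate 5, 53 for wt replicate 5 and 55 for wt replicate 12. In the other comparisons the range was 4529 to 5156, 5119 to 5758, 4856 to 5379 and 5644 to 6321.

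The level block, which leaves 2 wt arrays to compare with by construction, gave 782 genes in 1KI against wt, 417 in 1KI against 3aKO, 1583 in 3bKI against wt and 1232 in 3bKI against 3aKO (672, 391, 1482 and 1264 with a sex index beside it, as both wt arrays have Y-linked signal), and the higher-level arrays alone gave 174 in 1KI against wt and 133 in 3bKI against wt. Of the 5026 genes called in 1KI against wt, 95.3% kept their direction with the block, with a median ratio of 0.81 to the change without it, and of the 5318 in 3bKI against wt 98.0%, with a ratio of 0.81. These genes were chosen in the fit without the block, and both fits use the same knock-in arrays, so much of this agreement is built in. With RNA integrity as a covariate, whose values do not overlap between these groups, 605 genes passed in 3bKI against wt and 116 in 3bKI against 3aKO. Genes called without adjustment, with the block and with RNA integrity alike numbered 15, 631, 360, 459 and 102 in the 5 comparisons.

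The arrays share only a replicate number, as not every pair deviates together: across genes 6, 4 and 7 of 10 same-numbered pairs in 3aKO against wt, 1KI against wt and 1KI against 3aKO were correlated above 0.1, and 2 and 1 of 5 in 3bKI against wt and 3aKO, but 1, 4, 5, 2 and 0 best with their own number. Replicate block fits, which by construction use same-numbered arrays alone, gave 14 genes in 3aKO against wt, 1964 in 3bKI against wt and 4021 in 3bKI against 3aKO. The clock list lost its call in 3bKI against wt (mean -0.65) and 3aKO (-0.67), as did the heat shock (-0.23) and endothelial (0.10) lists against 3aKO. Same-numbered arrays did not always match in Xist and Y-linked signal. In 3bKI against 3aKO these fits took 3aKO replicates 1 to 5, all with high Xist, and 3bKI arrays of both kinds. The female-biased list passed there with a mean of -1.79, so pairing and sex cannot be told apart in that fit.

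The number of lists passing (3, 1, 3, 4 and 5) was 0 in all 5 comparisons with an estimated correlation, and 0, 0, 0, 1 and 0 among genes above the median signal, where fewer genes were tested. With a sex index it was 3 in 1KI against wt and 5 in 1KI against 3aKO, with the replicate block 4, 5 and, in 3bKI against 3aKO, 3, with the level block 4 and 5, with a sex index beside it 4, 5 and, in 3bKI against 3aKO, 3, and without 1KI replicate 6 3 and 5. Over its alternatives each passing list had a highest adjusted p of 1.00, and a lowest between 2.2e-06 (fatty acid oxidation genes, 3bKI against wt) and 0.023 (heat shock genes, 3bKI against 3aKO). Reversed in test direction, none passing, were the G1/S list with the level block in 1KI against 3aKO (adjusted p = 0.97, and 0.74 with a sex index) and in 3bKI against 3aKO (0.99), and the endothelial list with RNA integrity in 3bKI against 3aKO (0.54).

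Among genes called in either fit, those that reversed were Fga in 1KI against 3aKO with the level block (-0.006, and -0.018 with a sex index) and, in 3bKI against 3aKO, Afp (-0.45) and E2f3 (0.19) with the mean of the probe sets, and Gpr182 (-0.066) and Pecam1 (-0.039) with RNA integrity.

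The knockout score of 1KI (0.40) was 0.136 with fewer genes, 0.354 with more genes, -0.149 with the even-numbered arrays choosing, 0.264 with the sex index regressed out and 0.187 for genes above the median signal, each then below 3aKO (permutation p from 3.3e-04 to 0.038), and 0.236 to 0.468 without 1 array. That of 3bKI (-0.22) was 0.370 with the even-numbered arrays choosing and -0.051 with the sex index regressed out, each below 3aKO (exact permutation p = 0.0079 and 0.016), and lay between -0.330 and -0.108 without 1 array. Within 10 Mb of E2f3 the odds ratio in 3bKI against 3aKO was 0.553 (31 of 138 genes, Fisher's exact p = 0.0029), against 0.833 within 20 Mb. The values hold no detection calls, so signal over background was judged by the median signal: 23 of the 32 genes called in 3aKO against wt, 3497 of 5026 in 1KI against wt and 4186 of 5318 in 3bKI against wt lay above it.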

Other observations

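The lists below were singled out only after their values were seen, and so were the fits with the hybridization control level, with or without a sex index, and the list tests without 1KI replicate 6.

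Cholesterol synthesis genes passed as a list in both knock-ins with the hybridization control level as a block, each time against the same 2 wt arrays. Of the 20 genes tested, 4 rose (Srebf2 by 0.52, Idi1 by 0.46, Dhcr7 by 0.43 and Tm7sf2 by 0.29), Stard4 fell by 0.44 and 15 did not pass in 1KI against wt without the block (4 and 1 adjusted over the list alone, mean log2 change 0.14, list adjusted p = 0.11). In 3bKI against wt 2 rose (Srebf2 by 0.42 and Mvk by 0.41), Stard4 fell by 0.61 and 17 did not pass (2 and 1 adjusted over the list alone, mean 0.02, list adjusted p = 0.94). With the level as a block, which leaves 2 wt arrays to compare with, both with Y-linked signal, the list passed with a mean of 0.46 in 1KI and 0.34 in 3bKI against wt, and with a sex index beside the block it passed with 0.35 and 0.26. In 1KI it also passed with replicate numbers as a block (0.15) and without 1KI replicate 6 (0.19). With the level as a block the endothelial list passed in both knock-ins as well (0.16 and 0.33), and the fatty acid synthesis list in 1KI (0.23). Wt replicates 1 and 2 are the wt arrays of that level in both normalizations. Lists that passed in both knock-ins with the block were thus not observed independently in each. With an estimated correlation, without the block, the lowest adjusted p of any of the 33 lists was 1.00.

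Female-biased liver genes passed in both knock-ins against wt with a sex index as a covariate, with mean log2 changes over 17 genes of -0.72 in 1KI and -0.76 in 3bKI. Without the sex index it had adjusted p = 1.00 in both with an estimated correlation. With the preset correlation and no sex index the list did not pass in 1KI (adjusted p = 0.38), where 0 rose, 14 did not pass and Acot3 (-1.33), Abcd2 (-1.06) and Hao2 (-1.03) fell (0 and 3 adjusted over the list alone). In 3bKI against wt it did not pass either (adjusted p = 0.38). There Ntrk2 (0.86) and Cux2 (0.21) rose, Acot3 (-2.58), Hao2 (-1.84) and Abcd2 (-1.46) fell and 12 did not pass (2 and 3 adjusted over the list alone). Among the arrays of the higher hybridization control level the mean was 0.45 in 1KI and 0.31 in 3bKI, without passing, but the 2 wt arrays there both had Y-linked signal. With a sex index beside the level block it was -0.38 and -0.55, without passing. In 3bKI against wt the metallothionein genes Mt2 (-1.64) and Mt1 (-1.49) and the receptor gene Il6ra (-1.52) fell, while Saa1 (1.19) and Lcn2 (1.39) rose. The acute phase list, of which 6 rose, 5 fell and 16 did not pass there (7 and 6 adjusted over the list alone), did not pass (adjusted p = 0.81), with a median of -0.01 and a mean of 0.01.

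The third pattern is the lower Apob in 3aKO and 3bKI. With RNA integrity as a covariate the Apob change in 3aKO against wt was -0.87, next to -0.88 without. The SD of that covariate was 0.398 in 1KI, where replicate 6 stood at 1.75, and 0.050 in wt and 0.064 in 3aKO. Its slope thus rests largely on 1KI, and the fit cannot decide on a difference in RNA integrity between groups. A fault or variant under a single probe set stays open, since the dimmer Apob probe set changed by -0.511 times as much as the brighter in 3aKO against wt, the opposite way. In 3bKI against 3aKO both fell (-1.09 and -0.93). Against wt the dimmer had a change of -0.48 in 3bKI, without passing, and of -0.57 in 1KI (the brighter -0.01). The dimmer also differed by hybridization control level: wt replicates 1 and 2 read 10.99 and 11.06, the other wt arrays 11.40 to 12.34. The 1KI arrays averaged 11.16, and the 3bKI arrays 11.21 next to 10.95 and 11.02 for wt replicates 1 and 2 in their normalization. Neither knock-in thus averaged below the wt arrays of its level at the dimmer probe set. A variant of the Apob gene in the mixed background and a change in its transcript ends could each give the split in 3aKO, and neither was tested.

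To ask whether chance could give the counts of called genes, the arrays of each comparison were split anew in 100 ways, the real split included. In each comparison 1 split, the real one, called as many genes. It called 32 genes in 3aKO against wt and another split at most 1, and in 1KI against wt 5026 and 1207. The counts were 5636 and 751 in 1KI against 3aKO, 5318 and 2962 in 3bKI against wt, and 6218 and 2102 in 3bKI against 3aKO. Counts this high are thus rare among random splits of these arrays. The splits take the arrays as separate and exchangeable, which the labels do not establish, and they ignore hybridization control level and sex. They therefore cannot tell whether related arrays fell together by chance.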
